A study of Mus musculus with 28 samples.

How the data were processed

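RNA of 28 mouse libraries was measured by RNA-seq in 3 experiments: 6 libraries of LLC cells at 36 h, 12 at 32 h, and 10 of sorted day 16 cells, 5 from tumour cells and 5 from OT1 T cells. RNA was extracted with Trizol and libraries were made with a SMARTER mRNA kit, per the labels' protocols. The submitters' processing notes name STAR 2.6.1d, Salmon 0.14.1 for the 36 h libraries and 0.13.1 for the others, DESeq2 1.34.0 and the mm10 genome, without the role of each. The annotation release is not given in the sources used here.

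The deposited 36 h table holds a normalized count signal per gene, which the authors made with DESeq2 per its file name. The divisor differed between genes of a library, so whole reads could not be recovered and no count test was run. The deposited 32 h and day 16 tables hold TPM, which the authors scaled to 1000000 per library, so depth is unknown and no counting interval can be given. The authors' deposited comparison tables of the 32 h experiment give a log2 fold change with its standard error and an adjusted p-value per gene, and they are quoted as the authors' own. In the 32 h table, 24 columns of values had no sample in the labels and were not used. The labels of 2 libraries of BAY-876 with TNF give another compound number as treatment than their titles do, and both were grouped by title.

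Values were taken to log2(value + 1), so a fold change understates that of genes at low levels. Genes were kept at 10 normalized counts or 1 TPM or more in at least 3 libraries, 5 on day 16. limma 3.58.1 in R 4.3.3 was fitted with a mean-variance trend, the 12 libraries of the 32 h experiment in a single fit, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The 7 comparisons were BAY-876 against vehicle at 36 h, BAY-876 or TNF against control, the combination against each single treatment, the interaction, and OT1 against tumour cells. Each table was tested on its own. The interaction is the response to BAY-876 with TNF minus that without. Before the data were examined, 27 gene lists with 458 names were fixed, of which 7 names were absent from the tables, together with the groups, tests, named-gene rule and alternatives. Each list with at least 2 measured members was tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Counts adjusted over the list alone use Benjamini-Hochberg within the list. Each Slc2a gene of day 16 and the share of Slc2a1 in summed Slc2a values were compared by exact two-sided permutation of libraries.

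The genes named in the text follow a rule. They are the 8 highest and 8 lowest log2 fold changes among genes past the threshold, with libraries of the groups that do not overlap and a mean of at least 5 TPM or 50 normalized counts in the higher group. Predicted genes, mitochondrial transcripts and receptor segments were left out. The 4 genes with the smallest p of each list and every measured Slc2a gene were added. For the interaction the overlap condition was dropped. Some genes the rule names are not reported here. Gene coordinates come from GENCODE M21 on GRCm38, in which 96.4% of the symbols were found.

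No library was a copy of another: replicate libraries of a group correlated at 0.984 to 0.9892 at 36 h, 0.9853 to 0.989 at 32 h and 0.9141 to 0.9886 on day 16. Transcripts of the mitochondrial genome took 2.61 to 2.94%, 5.4 to 6.33% and 3.18 to 6.93% of the values. Replicate numbers recur across groups, but the labels do not say that a number marks a shared culture or mouse. The labels name no sequencing batch. The method was tested on simulated values with 50 genes changed at each size. At the 36 h design, 54% of changes of 0.5 log2 and 86% of changes of 1 were recovered, with 11 false calls. At the 32 h design 88% and 94% were recovered with 9 false calls, and on day 16 32% and 78% with 11. The simulated noise was independent between genes, and changes of both signs were placed in genes well above the filter. The real tables hold far more changed genes, so these rates need not carry over. Alternatives were another pseudocount (0.1 TPM or 10 counts), no filter, a mean of at least 5 TPM or 100 counts, quantile normalization, each library left out, the replicate number as a block, and fits of only the libraries compared.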

Results

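RNA was sequenced in 28 libraries of mouse cells that fell into 8 groups. LLC is a lung carcinoma cell line, BAY-876 is a small-molecule inhibitor of the glucose transporter GLUT1, which Slc2a1 encodes, and TNF is an inflammatory cytokine that signals through NF-kappaB. In the first culture experiment, LLC cells received vehicle or 200 nM BAY-876 for 36 h, with 3 libraries per group. In the second, 12 libraries held 4 groups of 3: control, BAY-876, TNF, and BAY-876 with TNF. These cells were given 200 nM BAY-876 or nothing for 24 h and then 20 ng/ml TNF or nothing for 32 h, and the labels leave open whether the inhibitor stayed on. The third experiment took 5 libraries of tumour cells and 5 of OT1 T cells, which are transgenic CD8 T cells that recognise an ovalbumin peptide. Both were sorted on day 16 from LLC tumours carrying ovalbumin and NGFR in mice that lack Rag1 and so make no T or B cells of their own, and activated OT1 cells had been transferred on day 9. Summed normalized counts per library ranged from 16847994 to 17134536 at 36 h, with 12829 to 12962 genes detected. The 32 h and day 16 values are TPM, which sum to 1000000 in each library, so their depth is unknown. Between 11884 and 12410 genes were detected per library at 32 h and between 12458 and 13428 on day 16. The labels do not say that replicates came from separate cultures or animals, so each p-value measures only the spread between these samples, which may be technical. Values below are mean ± SD, with n = 3 per group in culture and n = 5 on day 16, and in each pair the group named first in the comparison comes first.

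Glucose transporters of tumour cells and tumour-reactive T cells were compared on day 16, as the series design asks. Slc2a3, which encodes the high-affinity transporter GLUT3, stood at 69.4 ± 10.4 against 4.27 ± 1.07 TPM in OT1 cells against tumour cells. This was a 13.4-fold difference (log2 3.75, SE 0.15, limma adjusted p = 1.27e-09). Slc2a1 went the other way, with 60.7 ± 9.48 against 124 ± 32.8 TPM (log2 −0.99, SE 0.18, limma adjusted p = 0.000392). Less abundant transporters were also higher in OT1 cells, Slc2a6 at 7.12 ± 3.81 against 1.09 ± 0.133 TPM, Slc2a8 at 15.9 ± 4.33 against 6.99 ± 2.41 TPM and Slc2a9, which transports urate, at 4.4 ± 0.84 against 2.2 ± 0.665 TPM. In each of these 5 genes no OT1 library overlapped a tumour library. The exact two-sided permutation test gave p = 0.00794, the smallest that 5 against 5 allows, also after adjustment over the 5 genes. It takes the libraries as unpaired, while shared mice between tumour and OT1 libraries of the same number stay open. With same-numbered libraries paired, 0 of the 5 genes passed. With 5 pairs that test cannot reach the threshold, so it does not decide the question. Slc2a1 made up 38.3 ± 4.35% of the summed Slc2a TPM in OT1 cells against 87.5 ± 4.68% in tumour cells (exact permutation p = 0.00794, libraries again taken as unpaired). Slc2a10 averaged 0.306 ± 0.319 TPM in OT1 cells and 1.54 ± 0.726 in tumour cells and was below the filter. As a list, the family had 4 members higher and 1 lower in OT1 cells (4 and 1 adjusted over the list alone, camera adjusted p = 0.0978). The sodium-coupled glucose transporters had fewer than 2 measured members, too few to test. In GRCm38, Slc2a1 lies on chromosome 4 at 119108711 to 119137983 and Slc2a3 on chromosome 6 at 122727809 to 122801640. Slc2a6 lies on chromosome 2 at 27021363 to 27027998, Slc2a8 on chromosome 2 at 32972990 to 32982083 and Slc2a9 on chromosome 5 at 38349273 to 38503143, all 5 being protein-coding genes.

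Myeloid markers accompanied these differences. The mean over the myeloid list was 582 ± 601 TPM in OT1 libraries and 16.2 ± 3.28 in tumour libraries, and the OT1 libraries 1 to 5 read 127, 560, 250, 353 and 1618 TPM. Without OT1 replicates 2, 4 and 5, the libraries with the most myeloid transcripts and a choice made after the data were seen, log2 differences were 3.85 for Slc2a3, −1.17 for Slc2a1, 1.20 for Slc2a6 and 1.03 for Slc2a8. Slc2a9 then no longer passed, at log2 0.51 (limma adjusted p = 0.0558).

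**Figure D1:**
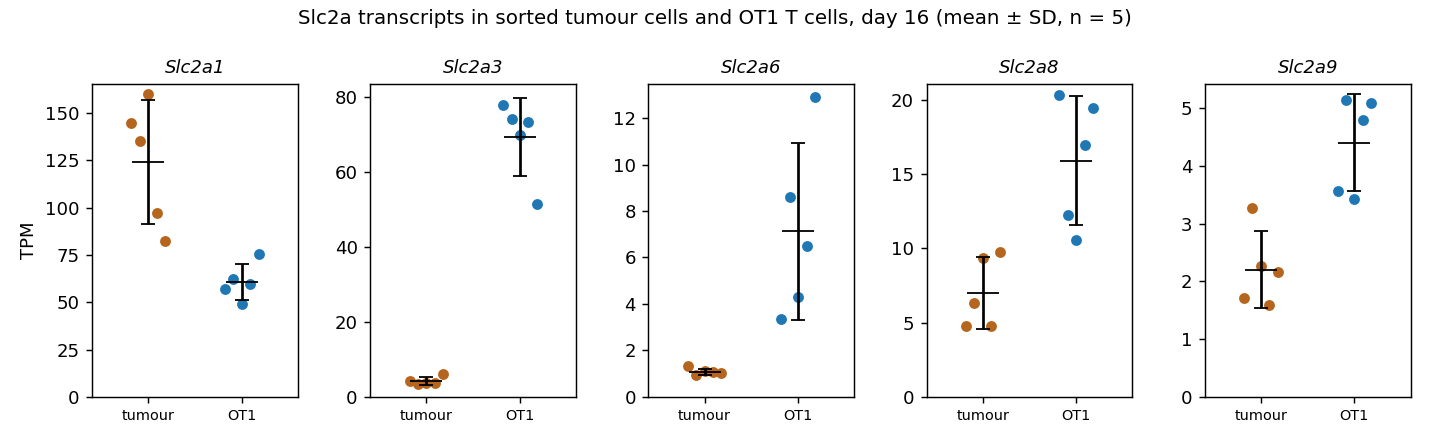
TPM of Slc2a1, Slc2a3, Slc2a6, Slc2a8 and Slc2a9 in tumour cells and OT1 T cells on day 16, one panel per gene. Points are libraries, bars show mean ± SD with n = 5, and in each panel the points of the 2 groups do not overlap.

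T cell genes held the largest differences between OT1 and tumour cells. Nkg7, a cytotoxic granule protein, reached 1228 ± 253 against 1.19 ± 0.921 TPM, and Gzmb, which encodes granzyme B, 971 ± 285 against 0.946 ± 0.911 TPM. Cd3e, a subunit of the T cell receptor complex, read 549 ± 117 against 0.177 ± 0.15 TPM. All 17 T cell identity genes were higher in OT1 cells (17 and 0 adjusted over the list alone, camera adjusted p = 1.93e-13, and adjusted p = 0.152 with an estimated correlation). Lck, the kinase proximal to the receptor, read 505 ± 69.1 against 3.13 ± 0.639 TPM. Cytotoxic effector genes were higher in 14 of 14 (14 and 0 adjusted over the list alone, camera adjusted p = 1.34e-09, and adjusted p = 0.152 with an estimated correlation). The cytokine gene Ifng read 232 ± 71.8 against 0.0195 ± 0.0436 TPM. Exhaustion genes were higher in 11 of 11 measured members (11 and 0 adjusted over the list alone, camera adjusted p = 4.22e-08, and adjusted p = 0.152 with an estimated correlation). The checkpoint receptor Pdcd1 read 416 ± 129.8 against 0.325 ± 0.147, Lag3 353 ± 74.2 against 0.424 ± 0.28 and Havcr2 95.2 ± 19.5 against 0.47 ± 0.0377 TPM. The direction of these T cell lists follows from the sort. No other state of T cells was measured, so they do not show whether the OT1 cells were exhausted. Tumour cells held more Rhox5, a homeobox gene on the X chromosome, at 44.5 ± 23.9 against 629 ± 44.6 TPM. Also lower in OT1 cells were Hmga2, an architectural chromatin protein, at 20.9 ± 13.2 against 288 ± 27.4 TPM, and the membrane protein Tm4sf1 at 12.2 ± 7.53 against 199 ± 27.9 TPM. Tumour cell markers were lower in 11 of 12 members and higher in 1 (1 and 11 adjusted over the list alone, camera adjusted p = 0.00243, and adjusted p = 0.306 with an estimated correlation). The receptor Met read 4.7 ± 0.45 against 42.1 ± 5.14 and keratin Krt18 6.64 ± 2.7 against 81.8 ± 6.32 TPM. The mean of the myeloid list in these libraries was 582 ± 601 against 16.2 ± 3.28 TPM.

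In the same libraries, whose myeloid mean was 582 TPM in OT1 against 16.2 in tumour cells, metabolic and stress genes also differed. Integrated stress response genes, the targets of the transcription factor ATF4, were lower in 19 of 27 and higher in 1 (1 and 19 adjusted over the list alone, camera adjusted p = 0.0304, and adjusted p = 0.547 with an estimated correlation). Atf4 itself read 200.2 ± 28.1 against 550.5 ± 99 TPM. Antioxidant genes were lower in 13 of 22 and higher in 3 (3 and 13 adjusted over the list alone, camera adjusted p = 0.0408, and adjusted p = 0.318 with an estimated correlation). The thioredoxin reductase Txnrd1 read 75.5 ± 7.53 against 276 ± 47.7 TPM. Cholesterol synthesis genes were lower in 17 of 21 and higher in 1 (1 and 17 adjusted over the list alone, camera adjusted p = 0.0253, and adjusted p = 0.547 with an estimated correlation). Cell cycle genes were lower in 17 of 25 (0 and 17 adjusted over the list alone, camera adjusted p = 0.0408, and adjusted p = 0.691 with an estimated correlation). The kinase Cdk1 read 112 ± 46.3 against 328 ± 15.6 TPM. TCA cycle genes were lower in 14 of 21 (0 and 14 adjusted over the list alone, camera adjusted p = 0.039, and adjusted p = 0.478 with an estimated correlation). Isocitrate dehydrogenase Idh2 read 23.6 ± 7.33 against 99.6 ± 5.24 TPM. Cell cycle and TCA cycle lists did not pass with quantile normalization (camera adjusted p = 0.0632 and 0.103). Death receptor and apoptosis genes were higher in 21 and lower in 5 of 29 (21 and 6 adjusted over the list alone, camera adjusted p = 0.00245, and adjusted p = 0.318 with an estimated correlation). The necroptosis kinase Ripk3 read 40.2 ± 5.75 against 0.48 ± 0.385 TPM. Txnip, an arrestin-like protein whose transcript follows glucose supply, was at 213 ± 112 against 47.2 ± 15.7 TPM (log2 2.08, SE 0.32).

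Several lists did not pass as a whole although single members did, again beside a myeloid mean of 582 against 16.2 TPM. Glycolysis genes were lower in 12 and higher in 4 of 21 (4 and 12 adjusted over the list alone, camera adjusted p = 0.288). The lactate exporter Slc16a3 read 137 ± 18.7 against 494 ± 89.6 and pyruvate kinase Pkm 1169 ± 59.9 against 2553 ± 203 TPM. Hypoxia genes were lower in 10 of 15 (1 and 10 adjusted over the list alone, camera adjusted p = 0.065). The prolyl hydroxylase Egln3 read 20.5 ± 7.1 against 167 ± 34.6 TPM. Oxidative phosphorylation was lower in 20 and higher in 6 of 36 (6 and 20 adjusted over the list alone, camera adjusted p = 0.227). Endoplasmic reticulum chaperones were lower in 13 and higher in 5 of 22 (5 and 13 adjusted over the list alone, camera adjusted p = 0.105). NF-kappaB genes were higher in 16 and lower in 9 of 31 (16 and 9 adjusted over the list alone, camera adjusted p = 0.136). Tnfaip3, an inhibitor of the pathway, read 230.4 ± 44.8 against 8.68 ± 1.89 TPM. For interferon genes the counts were 7 higher and 12 lower of 29 (6 and 12 adjusted over the list alone, camera adjusted p = 0.442). Antigen presentation genes were higher in 9 and lower in 2 of 14 (9 and 2 adjusted over the list alone, camera adjusted p = 0.0504), and passed as higher with quantile normalization (camera adjusted p = 0.0407). The pentose phosphate list had 1 higher and 4 lower of 8 (1 and 4 adjusted over the list alone, camera adjusted p = 0.368). The hexosamine list had 3 and 2 of 6 (3 and 2 adjusted over the list alone, camera adjusted p = 0.535). The glucose-sensing pair Txnip and Arrdc4 was higher in both (2 and 0 adjusted over the list alone, camera adjusted p = 0.187). Arrdc4 did not pass without OT1 replicates 2, 4 and 5 (log2 0.61, limma adjusted p = 0.0843, the lowest of its alternatives being 0.00039).

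Markers of other cells were measured in the same libraries. Myeloid genes were higher in OT1 libraries in 18 of 18 (18 and 0 adjusted over the list alone, camera adjusted p = 1.21e-06, and adjusted p = 0.403 with an estimated correlation). Lysozyme Lyz2 read 1952 ± 1875 against 23.6 ± 15.6 TPM and the integrin Itgax 49.3 ± 23.8 against 0.101 ± 0.0779 TPM. Fibroblast genes were lower in 6 of 6 (0 and 6 adjusted over the list alone, camera adjusted p = 0.0456, and adjusted p = 0.478 with an estimated correlation). Col3a1 read 31.3 ± 16.8 against 424 ± 129 TPM. The natural killer list had 3 higher and 1 lower of 4 (3 and 1 adjusted over the list alone, camera adjusted p = 0.0945). Its member Eomes also belongs to the exhaustion list, and Klra4 was higher in tumour cells at 1.54 ± 0.371 against 9.43 ± 1.33 TPM. None of 5 erythroid genes passed (0 and 0 adjusted over the list alone, camera adjusted p = 0.364). With the replicate number as a block the list passed as higher in OT1 cells (camera adjusted p = 0.0497). Without tumour replicate 4, Hba-a2 and Hbb-bs passed as higher in OT1 cells (log2 2.61 and 2.96, limma adjusted p = 0.0425 and 0.0443). Of the endothelial list Pecam1 alone was measured, at 48.8 ± 7.22 against 1.3 ± 1.31 TPM. In all, 10059 of 13511 genes differed between OT1 and tumour cells by limma at adjusted p under 0.05, 4061 higher and 5998 lower in OT1 cells. Without OT1 replicates 2, 4 and 5, 8161 of 12054 genes differed, 2491 higher and 5670 lower, and 7753 were called in both fits. The filter asks for 5 libraries and so leaves out genes detected only in OT1 cells once fewer OT1 libraries remain. Without any single OT1 library, 2892 to 3120 genes were higher among 12467 to 12489 tested, 3030 without replicate 1, which had the lowest myeloid mean.

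BAY-876 was set against vehicle at 36 h to describe the response of LLC cells to GLUT1 inhibition. Txnip dropped from 1332 ± 56.5 normalized counts in vehicle to 21.2 ± 7.53 with BAY-876 (log2 −5.96, SE 0.23). Its paralog Arrdc4 stood at 8.49 ± 4.46 against 53.7 ± 13 (log2 −2.63). Both are targets of the glucose-sensing factor MondoA (0 and 2 adjusted over the list alone, camera adjusted p = 0.000842, and adjusted p = 0.0984 with an estimated correlation). Integrated stress response genes rose in 24 of 27 measured members and fell in 0 (26 and 0 adjusted over the list alone, camera adjusted p = 4.4e-22, and adjusted p = 0.00952 with an estimated correlation). Among them were Chac1, which degrades glutathione, at 169.7 ± 10.8 against 15.7 ± 2.95 normalized counts, and the pseudokinase Trib3 at 984 ± 34.8 against 262 ± 53.4. Ddit3, which encodes CHOP, stood at 433 ± 13.9 against 171 ± 12.1, and Ddit4, an inhibitor of mTORC1, at 2879 ± 71.8 against 1406 ± 42. Slc2a1, the gene of the inhibited transporter, rose to 9779.8 ± 475 against 5104 ± 108 (log2 0.94, SE 0.05, limma adjusted p = 3.44e-05). It made up 95.4 ± 0.0475% of summed Slc2a counts against 91.8 ± 0.413% in vehicle (exact permutation p = 0.1, the smallest that 3 against 3 allows), and its gain of 3.61 points became 2.02 with Slc2a1 to Slc2a4 alone summed. The transporters Slc2a3, at 251 ± 23.4 against 248 ± 35.5, Slc2a8, Slc2a9 and Slc2a10 did not pass (limma adjusted p = 0.926, 0.805, 0.464 and 0.405). The family list had 1 riser of 5 (1 and 0 adjusted over the list alone, camera adjusted p = 0.347).

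Hypoxia response genes rose in 10 of 15 members (12 and 1 adjusted over the list alone, camera adjusted p = 2.3e-10, and adjusted p = 0.0984 with an estimated correlation). The stress-responsive gene Ndrg1 stood at 5118 ± 263 against 1639 ± 49.3 normalized counts, the angiogenic factor Vegfa at 5542 ± 541 against 3070.0 ± 147 and adrenomedullin Adm at 2709.7 ± 99 against 1572 ± 93.8. Endoplasmic reticulum chaperone and unfolded protein response genes rose in 9 of 22 (9 and 0 adjusted over the list alone, camera adjusted p = 0.000939, and adjusted p = 0.0984 with an estimated correlation). Herpud1 read 678 ± 23 against 411 ± 29.2, Xbp1 1364 ± 66.1 against 936 ± 27.2 and calreticulin Calr 10024 ± 484 against 7788 ± 180.1. Antioxidant genes rose in 6 of 22 (11 and 1 adjusted over the list alone, camera adjusted p = 0.00102, and adjusted p = 0.336 with an estimated correlation). Haem oxygenase Hmox1 read 1147 ± 30.3 against 646 ± 18.2 and the cystine transporter Slc7a11, which the stress response list also holds, 242 ± 48.5 against 112 ± 10.7. Glycolysis genes rose in 9 and fell in 1 of 21 (10 and 2 adjusted over the list alone, camera adjusted p = 0.00153, and adjusted p = 0.433 with an estimated correlation). Hexokinase Hk1 read 3278 ± 38.9 against 2415 ± 77.9. Oxidative phosphorylation rose in 2 of 36 (1 and 0 adjusted over the list alone, camera adjusted p = 0.000939, and adjusted p = 0.596 with an estimated correlation). The members were Cox4i1 and Uqcrq, and neither passed with any 1 vehicle library left out. Other large rises were Car6, a secreted carbonic anhydrase, at 70.6 ± 8.85 against 6.42 ± 2.92 and the actin-binding Avil at 64.3 ± 6.92 against 8.79 ± 4.46. The retinol transporter Stra6 reached 143 ± 8.38 against 40.2 ± 4.85 and the stress cytokine Gdf15 72.8 ± 11.7 against 17.5 ± 4.97.

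Genes that fell with BAY-876 at 36 h included Angptl4, an inhibitor of lipoprotein lipase, at 63.9 ± 18.8 against 184 ± 23.9 normalized counts. The transcription factor Egr3 stood at 79.3 ± 9.12 against 181 ± 12.5 and Pik3r3, a regulatory subunit of PI3 kinase, at 105 ± 19.1 against 236 ± 57.3. The growth factor Csf1 fell to 4312 ± 220.4 against 6179 ± 142 and the adhesion molecule Vcam1 to 641 ± 39.9 against 904 ± 47. The NF-kappaB list had 2 risers and 4 fallers of 26 (2 and 5 adjusted over the list alone, camera adjusted p = 0.534). Cholesterol synthesis showed 1 and 2 of 22 (1 and 2 adjusted over the list alone, camera adjusted p = 0.456). The demethylase Cyp51 read 918 ± 59.6 against 1289.5 ± 29.6. Cell cycle genes showed 1 and 2 of 25 (1 and 2 adjusted over the list alone, camera adjusted p = 0.347). TCA cycle genes showed 1 and 0 of 21 (0 and 0 adjusted over the list alone, camera adjusted p = 0.694). The member was Sdhb, which lost its call in most fits with a library left out (limma adjusted p from 0.0333 to 0.125 over all alternatives). Altogether 1868 of 12937 genes changed by limma, 949 higher and 919 lower, of which 88 rose and 29 fell at least 2-fold. In 4750 genes (36.7%) the groups did not overlap, where chance gives 10%. The count depended on the libraries kept, at 765, 714 and 648 without vehicle 1, 2 and 3. Without BAY-876 replicate 1, 2 or 3 it was 2394, 1351 and 1072.

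BAY-876 was compared with control again in the 32 h experiment, whose table was normalized separately. Txnip read 0.491 ± 0.177 against 43.5 ± 0.684 TPM (log2 −4.90, SE 0.19, limma adjusted p = 5.22e-08). Integrated stress response genes rose in 21 of 28 and fell in 0 (22 and 0 adjusted over the list alone, camera adjusted p = 5.2e-18, and adjusted p = 0.0852 with an estimated correlation). Ddit3 read 202 ± 15.4 against 74 ± 1.37 TPM, Atf4 890.1 ± 45.3 against 556 ± 10.9, Gdf15 17.5 ± 1.05 against 3.89 ± 0.543 and the mitochondrial folate enzyme Mthfd2 240.1 ± 11.3 against 134 ± 9.14. Cholesterol synthesis genes rose in 16 of 21 (16 and 0 adjusted over the list alone, camera adjusted p = 3.24e-11, and adjusted p = 0.0852 with an estimated correlation). The methylsterol monooxygenase Msmo1 read 47.7 ± 1.58 against 26.1 ± 0.916 and farnesyl diphosphate synthase Fdps 174 ± 13 against 104 ± 1.73. Fatty acid synthase Fasn reached 242 ± 13.5 against 87.4 ± 1.11 and Nadk2, a mitochondrial NAD kinase, 174 ± 13 against 42 ± 1.1. Slc2a1 rose to 121 ± 9.33 against 76.8 ± 3.1 TPM (log2 0.64, SE 0.10, limma adjusted p = 0.000446) and Slc2a8 fell to 6.31 ± 0.836 against 9.7 ± 0.481 (log2 −0.55). Slc2a3 at 5.55 ± 1.1 against 4.21 ± 0.617 did not pass (limma adjusted p = 0.0718) but did with quantile normalization (0.0183, the highest of all alternatives being 0.268). The Slc2a1 transcript made up 87.9 ± 1.3% of summed Slc2a TPM against 79.7 ± 1.63% in control (exact permutation p = 0.1, the smallest possible). This gain of 8.22 points became 1.30 with Slc2a1 to Slc2a4 alone summed. The family list counted 1 and 1 of 6 (1 and 1 adjusted over the list alone, camera adjusted p = 0.594).

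Cell cycle genes fell in 19 of 25 (1 and 19 adjusted over the list alone, camera adjusted p = 9.93e-06, and adjusted p = 0.0202 with an estimated correlation). The proliferation marker Mki67 read 59.3 ± 0.797 against 98.2 ± 0.217 TPM, topoisomerase Top2a 264 ± 8.05 against 358 ± 7.44 and the mitotic kinase Aurkb 147 ± 6.68 against 205 ± 6.12. Endoplasmic reticulum chaperones fell in 14 and rose in 1 of 22 (1 and 15 adjusted over the list alone, camera adjusted p = 0.000504, and adjusted p = 0.0804 with an estimated correlation). Hsp90b1 read 796 ± 13.7 against 1007 ± 8.43, the disulfide isomerase Pdia6 912 ± 31.1 against 1169 ± 20.6 and Sdf2l1 59.1 ± 5.34 against 108 ± 4.08. Interferon genes fell in 9 and rose in 1 of 14 (1 and 9 adjusted over the list alone, camera adjusted p = 0.0236, and adjusted p = 0.0941 with an estimated correlation). The RNA sensor Ddx58 read 4.85 ± 0.434 against 11.5 ± 1.05 and the transcription factor Irf1 8.3 ± 0.789 against 15.5 ± 1.56. Death receptor genes fell in 13 and rose in 3 of 26 (3 and 13 adjusted over the list alone, camera adjusted p = 0.153). Caspase Casp8 read 26.8 ± 1.06 against 47.4 ± 3.2 and the apoptosis effector Bax 193 ± 2.49 against 144 ± 4.86. Other large falls were Rras, a small GTPase, at 7.84 ± 1.12 against 33.2 ± 2.8, the protease Prtn3 at 0.283 ± 0.138 against 6.9 ± 1.26 and the phospholipase Pla2g7 at 6.49 ± 0.785 against 22.6 ± 0.756. The glycolysis list was split, 3 up and 7 down of 20 (3 and 7 adjusted over the list alone, camera adjusted p = 0.978). With quantile normalization 3 were up and 4 down. Hexokinase Hk2 read 49.3 ± 0.82 against 34.5 ± 1.04 and Pgk1 964 ± 23.6 against 1319.6 ± 20.5. Hypoxia genes did not pass as a list, with 4 up and 2 down of 15 (5 and 2 adjusted over the list alone, camera adjusted p = 0.0786). The same held for antioxidant genes, 3 and 6 of 22 (3 and 6 adjusted over the list alone, camera adjusted p = 0.978). NF-kappaB genes counted 2 and 7 of 29 (2 and 7 adjusted over the list alone, camera adjusted p = 0.638). In all, 4776 of 12780 genes changed by limma, 1473 higher and 3303 lower, while quantile normalization gave 2238 and 2305. The libraries of the groups did not overlap in 6509 genes (50.9%), where chance gives 10%. For BAY-876 the authors' deposited table calls 2303 higher and 2161 lower of 14148.

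Fold changes of BAY-876 at 36 h and 32 h were set side by side across 12086 genes, which are not independent replicates. The experiments differ in more than time. The 32 h cells had BAY-876 for 24 h before those 32 h, and the values are TPM against normalized counts. The comparison cannot tell these differences apart. Pearson r was 0.276 and Spearman rho 0.203. Both comparisons called 336 genes higher, where independent lists would share 111.7, and 332 lower, where they would share 244.1. Another 264 were called in opposite directions against 360.2. Of the 932 genes called in both, 71.7% moved the same way, Txnip, Slc2a1, Ddit3, Gdf15, Ndrg1 and Vegfa among them. Endoplasmic reticulum chaperones were a list called in opposite directions, both calls being lost with an estimated correlation (adjusted p = 0.0984 at 36 h and adjusted p = 0.0804 at 32 h). That difference itself was not tested.

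TNF alone was compared with control at 32 h. NF-kappaB genes rose in 27 of 29 and fell in 0 (27 and 0 adjusted over the list alone, camera adjusted p = 6.54e-22, and adjusted p = 7.34e-05 with an estimated correlation). The inhibitor Nfkbia, a feedback target of the pathway, reached 335 ± 12 against 43.7 ± 5.41 TPM and the chemokine Ccl2 1407 ± 21.1 against 218 ± 6.82. The subunit Nfkb2 read 95.9 ± 1.79 against 25.1 ± 0.405, the metalloprotease Mmp9 34.2 ± 2.21 against 0.342 ± 0.0913 and complement C3 36 ± 0.453 against 0.184 ± 0.0752. Antigen presentation genes rose in 9 of 14 (10 and 0 adjusted over the list alone, camera adjusted p = 2.8e-06, and adjusted p = 0.057 with an estimated correlation). The class I heavy chain H2-K1 read 230.1 ± 6.64 against 71.2 ± 5.07, its light chain B2m 706 ± 12 against 443 ± 10.3 and the peptide-loading protein Tapbp 322 ± 24.4 against 115 ± 17.7. The death receptor Fas stood at 9.15 ± 1.05 against 0.167 ± 0.154 and superoxide dismutase Sod2 at 412 ± 12.5 against 163 ± 1.17. The death receptor list counted 9 up and 10 down of 26 (9 and 10 adjusted over the list alone, camera adjusted p = 0.746). Txnip fell to 11.8 ± 3.95 against 43.5 ± 0.684 TPM (log2 −1.84, SE 0.19). Slc2a6 rose to 5.85 ± 1.83 against 0.88 ± 0.586 (log2 1.88) and Slc2a8 fell to 4.8 ± 0.368 against 9.7 ± 0.481. Slc2a3 at 4.85 ± 0.176 against 4.21 ± 0.617 did not pass (limma adjusted p = 0.308) but did with quantile normalization (0.0449, the highest of all alternatives being 0.67). Slc2a1 at 87.2 ± 2.17 against 76.8 ± 3.1 TPM did not pass (limma adjusted p = 0.161) but did in the authors' deposited table (log2 0.26, adjusted p = 6.95e-06). It also passed, at log2 0.18, without replicate 1 of the combination (limma adjusted p = 0.0247) and in a fit of only the 6 libraries compared (0.0138), while other alternatives reached 0.295. The Slc2a1 share was 82.7 ± 1.54% against 79.7 ± 1.63% (exact permutation p = 0.2), and its difference of 2.99 points became 0.81 with Slc2a1 to Slc2a4 alone summed. For the family list the counts were 1 and 1 of 6 (1 and 1 adjusted over the list alone, camera adjusted p = 0.871).

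**Figure D2:**
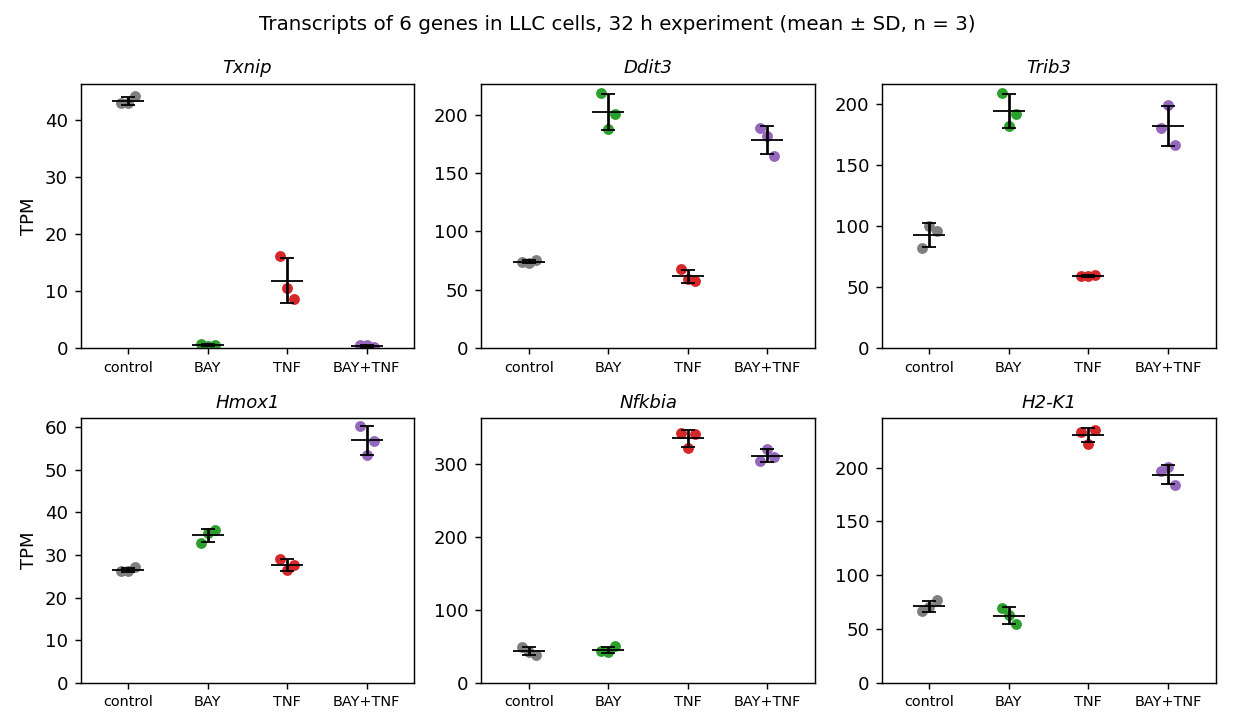
TPM of Txnip, Ddit3, Trib3, Hmox1, Nfkbia and H2-K1 in the control, BAY-876, TNF and BAY-876 with TNF groups at 32 h. Points are libraries and bars show mean ± SD with n = 3, with Nfkbia and H2-K1 higher in both groups given TNF and Ddit3 and Trib3 higher in both groups given BAY-876.

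Tumour cell markers fell with TNF in 9 of 12 and rose in 1 (1 and 9 adjusted over the list alone, camera adjusted p = 0.000206, and adjusted p = 0.0571 with an estimated correlation). Caveolin Cav1 read 136 ± 1.27 against 497 ± 44.3 TPM, keratin Krt8 162 ± 0.91 against 323 ± 10 and vimentin Vim 1414 ± 59.3 against 2746 ± 26.5. Endoplasmic reticulum chaperones fell in 17 of 22 (0 and 20 adjusted over the list alone, camera adjusted p = 1.03e-08, and adjusted p = 0.00571 with an estimated correlation). Pdia4 read 155 ± 2.83 against 279.9 ± 2.79 and Hsp90b1 699 ± 11.5 against 1007 ± 8.43. The largest falls also held the matrix protein Thbs1 at 0.906 ± 0.161 against 22.4 ± 1.3 and the surface antigen Ly6c1 at 26 ± 3.93 against 266 ± 8.59. Among the largest rises were the urea cycle enzyme Ass1 at 41.8 ± 1.53 against 2.62 ± 1.18 and the signalling adaptor Traf1 at 38 ± 3.43 against 0.315 ± 0.143. TCA cycle genes rose in 8 and fell in 3 of 21 (8 and 3 adjusted over the list alone, camera adjusted p = 0.0364, and adjusted p = 0.373 with an estimated correlation). Isocitrate dehydrogenase Idh3a read 68.8 ± 5.53 against 46.1 ± 3.56. The TCA list did not pass with quantile normalization (camera adjusted p = 0.435). Oxidative phosphorylation rose in 15 and fell in 2 of 36 (15 and 2 adjusted over the list alone, camera adjusted p = 0.000632, and adjusted p = 0.373 with an estimated correlation). Cytochrome c Cycs read 142 ± 4.83 against 86.9 ± 4.46. With quantile normalization 5 members of this list rose and 4 fell (camera adjusted p = 0.435). Integrated stress response genes counted 6 up and 14 down of 28 (6 and 14 adjusted over the list alone, camera adjusted p = 0.147). Atf5 read 15.9 ± 2.02 against 35.8 ± 1.3 and Chac1 11.4 ± 0.692 against 19.2 ± 0.404. The stress list passed as lower with quantile normalization (camera adjusted p = 0.0182). Cholesterol genes counted 7 and 4 of 21 (7 and 4 adjusted over the list alone, camera adjusted p = 0.122). Interferon genes counted 3 and 6 of 14 (3 and 7 adjusted over the list alone, camera adjusted p = 0.458). Glycolysis genes counted 7 and 5 of 20 (7 and 5 adjusted over the list alone, camera adjusted p = 0.458). Lactate dehydrogenase Ldha read 1974 ± 47.9 against 1532 ± 17.3. TNF changed 5826 of 12780 genes by limma, 2485 higher and 3341 lower, of which 145 rose and 405 fell at least 2-fold, while quantile normalization gave 2877 higher and 2742 lower. No overlap of libraries was seen in 7140 genes (55.9%) against 10% by chance. For TNF the authors' deposited table calls 3061 higher and 2707 lower of 15534.

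TNF was also set against its absence in cells given BAY-876. NF-kappaB genes again rose in 27 of 29 and fell in 0 (27 and 1 adjusted over the list alone, camera adjusted p = 8.36e-22, and adjusted p = 7.48e-05 with an estimated correlation). Mmp9 read 29.9 ± 0.331 against 0.23 ± 0.0717 TPM, Ccl2 1442 ± 121 against 293 ± 21.6 and the acute phase protein Saa3 28.4 ± 3.72 against 1.16 ± 0.485. Antigen presentation genes rose in 8 of 14 (8 and 0 adjusted over the list alone, camera adjusted p = 4.09e-05, and adjusted p = 0.0595 with an estimated correlation). H2-K1 read 194 ± 8.61 against 62.4 ± 7.6. Antioxidant genes rose in 13 and fell in 4 of 22 (14 and 4 adjusted over the list alone, camera adjusted p = 0.00272, and adjusted p = 0.0595 with an estimated correlation). Hmox1 read 56.9 ± 3.4 against 34.6 ± 1.63 and Sod2, which the NF-kappaB list also holds, 457 ± 30.6 against 143 ± 7.66. Integrated stress response genes rose in 14 and fell in 3 of 28 (15 and 4 adjusted over the list alone, camera adjusted p = 0.00993, and adjusted p = 0.659 with an estimated correlation). Atf3 read 24.3 ± 1.71 against 8.02 ± 1.43 and Slc7a11 9.02 ± 1.37 against 3.21 ± 0.254. The stress list did not pass with quantile normalization (camera adjusted p = 0.228). Chaperones fell in 16 of 22 (0 and 16 adjusted over the list alone, camera adjusted p = 6.75e-06, and adjusted p = 0.0206 with an estimated correlation). The transcription factor Xbp1 read 45.8 ± 2.55 against 93.1 ± 1.15. Tumour cell markers fell in 9 and rose in 1 of 12 (1 and 9 adjusted over the list alone, camera adjusted p = 4.09e-05, and adjusted p = 0.0498 with an estimated correlation). Cav1 read 110.4 ± 5.42 against 456 ± 8.08 and Krt8 97.5 ± 1.38 against 221 ± 4.44. Hypoxia genes counted 1 up and 8 down of 15 (1 and 8 adjusted over the list alone, camera adjusted p = 0.0737), and passed as lower with quantile normalization (camera adjusted p = 0.0243). The mitophagy receptor Bnip3 read 29.4 ± 7.65 against 74.1 ± 5.53. TCA cycle genes rose in 9 of 21 (9 and 0 adjusted over the list alone, camera adjusted p = 0.0204, and adjusted p = 0.376 with an estimated correlation). They did not pass with quantile normalization (camera adjusted p = 0.422). Oxidative phosphorylation rose in 12 and fell in 3 of 36 (12 and 3 adjusted over the list alone, camera adjusted p = 0.0272, and adjusted p = 0.646 with an estimated correlation). Quantile normalization turned the list to 4 and 6, in the opposite direction (camera adjusted p = 0.893). Slc2a6 rose to 4.3 ± 0.358 against 0.402 ± 0.1 and Slc2a8 fell to 2.41 ± 0.0214 against 6.31 ± 0.836. Slc2a9 fell to 0.551 ± 0.2 against 1.41 ± 0.568 (log2 −0.62, limma adjusted p = 0.0192). Its call was lost with quantile normalization, without BAY-876 replicate 1 and without replicate 1 of the combination (limma adjusted p = 0.0755, 0.0833 and 0.0671, the lowest of all alternatives being 0.0106). The family list counted 1 and 2 of 6 (2 and 3 adjusted over the list alone, camera adjusted p = 0.901). Slc2a3 at 7.22 ± 0.738 against 5.55 ± 1.1 did not pass (limma adjusted p = 0.0561) but did with quantile normalization, without BAY-876 replicate 2 and without replicate 2 of the combination (0.0125, 0.0115 and 0.0417, the highest of all being 0.185). Slc2a1 at 104 ± 18.6 against 121 ± 9.33 did not pass (log2 −0.23, limma adjusted p = 0.0831), nor did Txnip at 0.431 ± 0.181 against 0.491 ± 0.177. Slc2a1 passed as lower without replicate 1 of the combination (log2 −0.37, limma adjusted p = 0.00103) and with quantile normalization (log2 −0.29, adjusted p = 0.0239), while other alternatives reached 0.295. By limma 5644 of 12780 genes changed, 2469 higher and 3175 lower, against 2851 and 2690 with quantile normalization. The authors' deposited table calls 2796 higher and 2530 lower of 14662.

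BAY-876 was last compared in the presence of TNF. All 28 measured integrated stress response genes rose (28 and 0 adjusted over the list alone, camera adjusted p = 4.66e-33, and adjusted p = 0.0268 with an estimated correlation). Ddit3 read 178 ± 12 against 61.4 ± 5.28 TPM, Trib3 182 ± 16.3 against 59.2 ± 0.621, Chac1 32.6 ± 1.25 against 11.4 ± 0.692, Atf5 51 ± 5.02 against 15.9 ± 2.02 and Atf4 1038 ± 50.9 against 566 ± 9.39. The cysteine-producing enzyme Cth stood at 47.5 ± 2.66 against 13.5 ± 1.27 and the mitochondrial folate enzyme Aldh1l2 at 114 ± 17.2 against 30.3 ± 4.31. Antioxidant genes rose in 13 and fell in 2 of 22 (15 and 4 adjusted over the list alone, camera adjusted p = 2.52e-05, and adjusted p = 0.0268 with an estimated correlation). Hmox1 read 56.9 ± 3.4 against 27.7 ± 1.36 and ferritin Fth1 4312 ± 83.9 against 3457 ± 71.5. Pentose phosphate genes rose in 5 and fell in 1 of 8 (5 and 1 adjusted over the list alone, camera adjusted p = 0.00359, and adjusted p = 0.0546 with an estimated correlation). The dehydrogenase Pgd read 263 ± 5.73 against 229 ± 8.91. Cholesterol synthesis genes rose in 7 and fell in 2 of 21 (7 and 2 adjusted over the list alone, camera adjusted p = 0.00205, and adjusted p = 0.328 with an estimated correlation). Squalene epoxidase Sqle read 59.7 ± 5.66 against 44.5 ± 0.426. Cell cycle genes fell in 15 and rose in 1 of 25 (1 and 16 adjusted over the list alone, camera adjusted p = 0.000924, and adjusted p = 0.0268 with an estimated correlation). Mki67 read 49.6 ± 2.33 against 76.1 ± 3.67 and Plk1 95.5 ± 0.706 against 128 ± 1.25. Antigen presentation fell in 9 of 14 (0 and 10 adjusted over the list alone, camera adjusted p = 0.0165, and adjusted p = 0.215 with an estimated correlation). Tapbp read 228 ± 9.31 against 322 ± 24.4 and the peptide transporter Tap1 6.16 ± 0.482 against 10.3 ± 0.673. Tumour cell markers fell in 8 and rose in 2 of 12 (2 and 9 adjusted over the list alone, camera adjusted p = 0.0149, and adjusted p = 0.197 with an estimated correlation). Krt8 read 97.5 ± 1.38 against 162 ± 0.91. NF-kappaB genes counted 4 up and 10 down of 29 (4 and 11 adjusted over the list alone, camera adjusted p = 0.628). Vcam1 read 38.6 ± 3.26 against 59.6 ± 2.27. Glycolysis genes counted 2 and 9 of 20 (3 and 12 adjusted over the list alone, camera adjusted p = 0.0799). They passed as lower with quantile normalization (camera adjusted p = 0.045). Death receptor genes counted 4 and 13 of 26 (4 and 14 adjusted over the list alone, camera adjusted p = 0.114). Casp8 read 22.6 ± 0.4 against 37.6 ± 1.42. Txnip fell to 0.431 ± 0.181 against 11.8 ± 3.95 and Slc2a3 rose to 7.22 ± 0.738 against 4.85 ± 0.176. Slc2a8 fell to 2.41 ± 0.0214 against 4.8 ± 0.368, and the family list counted 1 and 1 of 6 (1 and 1 adjusted over the list alone, camera adjusted p = 0.628). Slc2a1 at 104 ± 18.6 against 87.2 ± 2.17 did not pass (limma adjusted p = 0.0918) but did in the authors' deposited table (log2 0.34, adjusted p = 0.00179). It also passed without replicate 3 of the combination (log2 0.33, limma adjusted p = 0.0287) and with quantile normalization (log2 0.28, adjusted p = 0.0381), while other alternatives reached 0.298. By limma 4341 of 12780 genes changed, 1323 higher and 3018 lower, against 1860 and 2048 with quantile normalization. The authors' deposited table calls 1875 higher and 1746 lower of 13001.

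**Figure D3:**
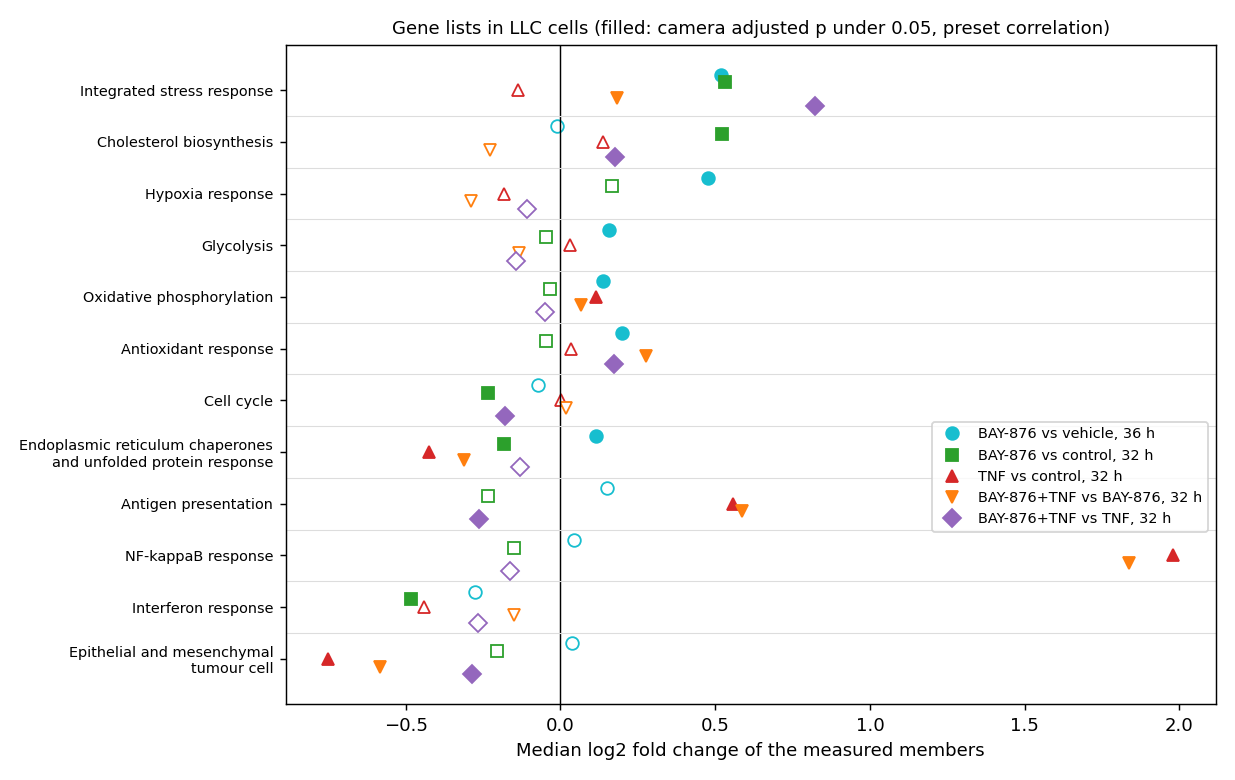
Median log2 fold change of 12 gene lists in the 5 culture comparisons, with BAY-876 at 36 h and 32 h, TNF alone, TNF after BAY-876, and BAY-876 under TNF. Filled points mark lists with a camera adjusted p under 0.05 at the preset correlation, the NF-kappaB list standing highest in both TNF comparisons.

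The interaction asked whether the response to BAY-876 differed with TNF on the log2(TPM+1) scale. Integrated stress response genes had a positive interaction, a higher log2 response to BAY-876 with TNF than without, in 7 members and a negative in 0 of 28 (22 and 0 adjusted over the list alone, camera adjusted p = 9.39e-18, and adjusted p = 0.0881 with an estimated correlation). Asparagine synthetase Asns read 266 ± 6.17 TPM in control, 286 ± 5.63 with BAY-876, 223 ± 15.3 with TNF and 330.3 ± 9.18 with both (interaction log2 0.46, SE 0.07, limma adjusted p = 0.00648). In the same order Chac1 read 19.2 ± 0.404, 34.6 ± 3.65, 11.4 ± 0.693 and 32.6 ± 1.25 TPM. The interaction of antioxidant genes was positive in 5 of 22 (13 and 0 adjusted over the list alone, camera adjusted p = 1.72e-12, and adjusted p = 0.00241 with an estimated correlation). Hmox1 read 26.6 ± 0.462, 34.6 ± 1.63, 27.7 ± 1.36 and 56.9 ± 3.4 TPM, with the larger difference under TNF. Txnrd1 read 205 ± 3.73, 140.1 ± 0.423, 203 ± 2.9 and 189.6 ± 10.3 TPM, a smaller difference under TNF, and Sod2 163 ± 1.17, 143 ± 7.66, 412 ± 12.5 and 457 ± 30.6 TPM, lower with BAY-876 without TNF and higher with it. The Sod2 call was lost in most fits with a library left out (limma adjusted p from 0.0141 to 0.102 over all alternatives). Cholesterol synthesis genes had a negative interaction in 3 of 21 (0 and 11 adjusted over the list alone, camera adjusted p = 7.26e-12, and adjusted p = 0.0881 with an estimated correlation). Nadk2 read 42 ± 1.1, 174 ± 13, 30 ± 4.67 and 48.3 ± 3.37 TPM (interaction log2 −1.35). The pentraxin Nptx1 read 21.9 ± 0.0776, 62.3 ± 2.19, 19.1 ± 0.155 and 25 ± 1.58. Saa3 read 1.81 ± 0.762, 1.16 ± 0.485, 11.1 ± 0.455 and 28.4 ± 3.72. Txnip read 43.5 ± 0.684, 0.491 ± 0.177, 11.8 ± 3.95 and 0.431 ± 0.181 TPM, an interaction of 1.78. Both values with BAY-876 lay below 1 TPM, near the floor of the log scale, so a lower start under TNF may by itself give this interaction. With a pseudocount of 0.1 the interaction was 1.94 for Saa3 and 1.75 for Txnip but did not pass (limma adjusted p = 0.0619 and 0.0881, the highest of all alternatives, the lowest being 0.00942 and 0.00295). No Slc2a gene passed, Slc2a1 having an interaction of −0.41 (limma adjusted p = 0.193). A single library decided this, since without replicate 1 of the combination the Slc2a1 interaction was −0.55 (limma adjusted p = 0.0148, against up to 0.331 under other alternatives).

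Other lists in the interaction had few members past the threshold. Glycolysis had 1 above and 1 below of 20 (1 and 6 adjusted over the list alone, camera adjusted p = 0.000384, and adjusted p = 0.488 with an estimated correlation). The members were the lactate transporter Slc16a1 and the isomerase Tpi1. Each lost its call in most fits with a library left out, with limma adjusted p from 0.0104 to 0.107 for Slc16a1 and 0.0148 to 0.0744 for Tpi1 over all alternatives. The pentose phosphate list had 1 above of 8 (2 and 0 adjusted over the list alone, camera adjusted p = 0.00728, and adjusted p = 0.0881 with an estimated correlation). The member was Pgd, which lost its call without control 1 or 2, BAY-876 replicate 1 or 2, TNF replicate 2 or replicate 2 of the combination (limma adjusted p from 0.0186 to 0.0704 over all alternatives). Hexosamine genes had 0 and 0 of 6 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0174, and adjusted p = 0.154 with an estimated correlation). Chaperones had 1 above of 22 (1 and 0 adjusted over the list alone, camera adjusted p = 0.0162, and adjusted p = 0.122 with an estimated correlation). The member was the chaperone Hspa5, which did not pass with quantile normalization, without a filter or in most fits with a library left out (limma adjusted p from 0.0146 to 0.307 over all alternatives). Cell cycle had 0 and 0 of 25 (0 and 0 adjusted over the list alone, camera adjusted p = 0.0413, and adjusted p = 0.122 with an estimated correlation). This list did not pass with quantile normalization (camera adjusted p = 0.0755). By limma 199 of 12780 genes had an interaction, 94 positive and 105 negative, and 1899 at an unadjusted p under 0.05. The count was 127 without control 1, 117 without control 2, 115 without BAY-876 replicate 2, 119 without BAY-876 replicate 3, 110 without TNF replicate 2 and 122 without TNF replicate 3. Leaving out 1 of the other libraries gave from 135 without BAY-876 replicate 1 to 250 without replicate 3 of the combination.

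Across the 12780 genes, fold changes of BAY-876 with and without TNF had a Pearson r of 0.627 and a Spearman rho of 0.662, and genes are not independent replicates. Both called 851 genes higher and 2142 lower, where independent lists would share 152.5 and 780. Opposite calls numbered 39 against 689.8. For TNF with and without BAY-876 r was 0.794 and rho 0.77. Here 1891 genes were higher and 2395 lower in both against 480.1 and 830, and 37 opposite against 1262.8. NF-kappaB genes such as Mmp9 and Nfkb2 lay among the shared rises of the TNF comparisons, and stress response genes such as Ddit3 and Trib3 among those of BAY-876.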

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

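The tests of technical explanations below were chosen only after the result was seen, and so was the removal of both main effects before the libraries were regrouped for the interaction.

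The response to BAY-876 differed with TNF in 199 genes by limma. After both main effects were taken out, 1 of 100 splits of the libraries, the real one, gave as many, the highest other split giving 3. Other splits carry the interaction into the spread within groups, which keeps their counts low. The splits show only that the count follows the treatment groups of these libraries, which may be technical replicates. The interaction on the log2 scale was 1.78 for Txnip, 1.65 for Saa3, 1.41 for Mmp23, 1.21 for Plxnd1, 1.19 for Enpp2, 1.14 for Srl, 1.07 for Acer3 and 1.07 for Fbn1. It was −1.72 for Wincr1, −1.35 for Nadk2, −1.12 for C3, −1.09 for Nptx1, −1.06 for Slco4a1, −1.0 for Adamts7, −0.97 for Clec1a and −0.95 for Col8a1. With a pseudocount of 0.1 it was 1.75 for Txnip, 1.94 for Saa3, 1.81 for Mmp23 and −1.41 for C3, and none of these passed (limma adjusted p = 0.0881, 0.0619, 0.0508 and 0.266). Mmp23 and C3 also lost the call in other fits, Mmp23 in most of those with a library left out, with adjusted p from 0.0218 to 0.108 for Mmp23 and 0.00971 to 0.266 for C3 over all alternatives. Enpp2 lost it without a filter and without BAY-876 replicate 2 (limma adjusted p = 0.0503 and 0.0557, the lowest of all being 0.0136). Txnip stood at 0.491 and 0.431 TPM in the groups given BAY-876, near the floor of the log scale, and Saa3 and C3 were low in control. A floor effect was not tested for these genes. Among gene lists, camera adjusted p for the interaction was 9.39e-18 for the integrated stress response, 1.72e-12 for antioxidant genes, 7.26e-12 for cholesterol synthesis, 0.000384 for glycolysis, 0.00728 for pentose phosphate, 0.0162 for chaperones, 0.0174 for hexosamine and 0.0413 for the cell cycle. With an estimated correlation the antioxidant list alone passed, at an adjusted p of 0.00241.

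The first pattern is the positive interaction of 12 called integrated stress response and antioxidant genes, Asns, Atf5, Chac1, Gars, Slc3a2, Slc7a3, Trib3, Fth1, Hmox1, Nfe2l2, Sod2 and Txnrd1. Of these Txnrd1 differed less with BAY-876 under TNF than without it. The means of Sod2 and Nfe2l2 were lower with BAY-876 without TNF and higher with BAY-876 under TNF. With both treatments Atf5, Chac1, Fth1 and Trib3 did not exceed BAY-876 alone, Atf5 reading 51.03 against 70.15 TPM and Trib3 181.7 against 194. These genes were lower with TNF alone than in control, Atf5 at 15.9 against 35.83 TPM. Slc3a2 was nearly equal at 344 against 343.1 TPM. Asns, Gars, Hmox1, Nfe2l2, Slc7a3, Sod2 and Txnrd1 were higher with both treatments than with BAY-876 alone. Values near the floor of the log scale are argued against, since 12 of 12 had a mean of at least 10 TPM in each of the 4 groups, the lowest being 11.4. Scaling of TPM is argued against as the whole cause, since with quantile normalization, which moved the count of all interaction genes from 199 to 264, 12 of 12 kept at least 88.8% of their interaction and the median moved from 0.45 to 0.41. Trib3 at 0.53 (SE 0.12) became 0.48 (SE 0.11) and Nfe2l2 at 0.30 (SE 0.06) became 0.27 (SE 0.07), and these slightly smaller values no longer passed (limma adjusted p = 0.0522 and 0.0669). A biological interaction of both treatments, the design's own factor, remains open as a hypothesis.

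The second pattern is the set of glucose transporter differences on day 16, where RNA of other cells in the OT1 sort is a candidate explanation. The most abundant myeloid markers read 390 to 5129 TPM for Lyz2, 448 to 6279 for Cd74 and 88.0 to 1675 for C1qa over the OT1 libraries, although the cells had been sorted. The slope of log2 TPM on the log2 myeloid mean over the 5 OT1 libraries was −0.15 for Slc2a3 (−0.18 to −0.03 with each library left out) and 0.13 for Slc2a1 (0.08 to 0.2), which argues against myeloid RNA as the source of either level. For Slc2a6 the slope was 0.56 (0.53 to 0.66), so it rose with the myeloid mean but less than in proportion to it. The Slc2a6 difference may therefore come partly from myeloid cells, while the cell type itself stays open and untested. Tumour RNA as the source of Slc2a1 is argued against by 2 of 7 abundant tumour markers, Krt8 at 7.57% and Cav1 at 8.50% of their tumour level, against 49.0% for Slc2a1. The rest stood higher, Axl at 18.7%, Spp1 at 24.1%, S100a6 at 32.4%, Vim at 37.2% and Lgals1 at 44.2% (34.29 to 50.35% over the OT1 libraries). Tumour RNA at the level of Slc2a1 would bring every tumour transcript to at least that percentage, so the lowest markers set the limit.

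The third pattern is the excess of lower over higher genes with BAY-876 at 32 h, where 30.8% of the changed genes were higher. With quantile normalization 49.3% were higher, so scaling of TPM may produce the excess, although a true decrease of many genes would be removed as well. The same normalization did not force an even split on day 16, where 40.4% became 41.7%. In the 32 h experiment it brought every comparison near even. There 42.7% became 51.2% for TNF, 43.7% became 51.5% for TNF after BAY-876 and 30.5% became 47.6% for BAY-876 under TNF. In the authors' deposited table, with its own normalization over 14148 genes, the share was 51.6%. That normalization may also have removed a true decrease, so the share does not separate it from scaling of TPM. No biological explanation of the excess was tested.

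The chaperone list was called in opposite directions with BAY-876 in the culture experiments, with 9 of 22 members higher at 36 h and 14 of 22 lower at 32 h, and both calls were lost with an estimated correlation (adjusted p = 0.0984 and adjusted p = 0.0804). The mean log2 change of the list was 0.15 in the lowest library at 36 h and −0.20 in the highest at 32 h, and this difference was not tested. The experiments also differ in exposure to BAY-876 and in normalization, so it cannot be read as an effect of time.

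Single libraries stood apart from the rest of their group in 4 of 62 sets of 5 values, by Dixon's ratio above 0.71, which chance gives in about 1 of 20. Tumour replicate 5 held 248 TPM of Tm4sf1 against 182 to 193 in the others, and tumour replicate 1 held 72.0 TPM of Platr16 against 47.1 to 53.6. The natural killer list averaged 2.29 TPM in tumour replicate 1 against 1.89 to 1.93, and the erythroid list 180 TPM in tumour replicate 4 against 2.02 to 36.2.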

How the results depend on the processing

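The fit without OT1 replicates 2, 4 and 5 was chosen only after the result was seen, and the other alternatives were planned. Of the named genes' values under all alternatives, 11145 kept direction and side of the threshold, 275 lost and 63 gained the call, counting a change of sign only where a call was made. Of the gene list tests, 396 kept their side of the threshold, including lists that were never called. Another 49 lost and 10 gained the call, 42 of the losses with an estimated correlation. With an estimated correlation, 1 of 7 called lists still passed at 36 h, 1 of 5 for BAY-876 at 32 h and 2 of 6 for TNF. For TNF after BAY-876 it was 3 of 8 and for BAY-876 under TNF 3 of 7. For the interaction 1 list passed and on day 16 0. With quantile normalization the oxidative phosphorylation list reversed for TNF after BAY-876 (adjusted p = 0.893), and the cause was not tested.

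With each library left out, counts of genes ranged from 648 to 2394 at 36 h, 3886 to 4921 for BAY-876 at 32 h, 5054 to 5892 for TNF, 4898 to 5622 for TNF after BAY-876, 3579 to 4227 for BAY-876 under TNF, 110 to 250 for the interaction and 8711 to 9396 on day 16. The lowest counts were 648 without vehicle 3 and 110 without TNF replicate 2, fits with fewer samples. Slc2a genes past the exact test stayed at 5. The Slc2a1 share differed by −51.2 to −48.2 points on day 16, 3.4 to 3.81 at 36 h, and at 32 h by 7.71 to 9.16, 2.26 to 3.93 and 4.97 to 7.13 for BAY-876, TNF and both. Summing Slc2a1 to Slc2a4 alone, a sum of fewer genes, gave 2.02 points at 36 h and 1.30, 0.81 and −0.53 at 32 h. Correlations ranged from 0.593 to 0.622 for BAY-876 with and without TNF, 0.77 to 0.791 for TNF and 0.25 to 0.274 between the 36 h and 32 h experiments. The first 2 were 0.692 and 0.843 with the stricter filter. For the range between the 36 h and 32 h experiments only the 36 h libraries were left out in turn.

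With the replicate number as a block, 1563 genes were called at 36 h, 4710 for BAY-876 and 5773 for TNF at 32 h, 5598 for TNF after BAY-876, 4254 for BAY-876 under TNF, 174 for the interaction and 9930 on day 16. On day 16 the block gave calls to the hypoxia, antigen presentation and erythroid lists (camera adjusted p = 0.0481, 0.0493 and 0.0497), and to 4 hemoglobin genes (limma adjusted p from 0.000179 to 0.00233), the erythroid list being higher in OT1 libraries in 5 of 5 same-numbered pairs. The Slc2a exact test, then a sign-flip test whose smallest p is 0.0625, called 0 of 5. Same-numbered libraries deviated with correlations of −0.074 to −0.019 at 36 h, −0.192 to 0.12 at 32 h and 0.045 to 0.111 on day 16. Not every pair exceeded 0.1, so the main tests did not pair libraries by number. In no experiment did every library correlate most with its own number. On day 16, however, every same-numbered pair was positive, against −0.174 to 0.113 for other pairs, and most libraries correlated most with their own number. Shared mice on day 16 therefore stay open. No gene count moved by over 1.5 times under the block. Tests on recovered whole reads with edgeR or DESeq2 were not run, because whole reads could not be recovered. Depth is unknown for TPM, so low genes were limited by the filter alone.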

Other observations

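The gene groups below were looked at only after the data were seen, 5 in all, while the splits of libraries were planned tests.

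Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were lower in OT1 than in tumour cells in 18 of 18 members, with a median log2 difference of −1.14, beside a myeloid list mean of 582 against 16.2 TPM. In culture they rose in 14 and fell in 3 with BAY-876 under TNF, and rose in 11 and fell in 0 with TNF after BAY-876. With BAY-876 alone the counts were 8 and 2 at 32 h and 4 and 1 at 36 h. With TNF alone they were 4 and 2, and 4 and 6 with quantile normalization. Fatty acid synthesis genes rose in 6 of 8 members with BAY-876 at 32 h, with Fasn at log2 1.46, while Acss2 fell, at −0.68. At 36 h 2 rose and 0 fell, Fasn standing at 0.26, and with BAY-876 under TNF 2 rose and 1 fell. TNF alone raised 4 and lowered 4. TNF after BAY-876 lowered 5 and raised 1, with the desaturases Scd1 at −1.34 and Scd2 at −1.12 and the regulator Srebf1 at −0.96.

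Cytosolic ribosomal protein genes rose with BAY-876 at 32 h in 56 of 82 and fell in 1, and in 32 and 2 with quantile normalization. At 36 h 27 rose and 0 fell. With TNF alone 22 rose and 6 fell, and with TNF after BAY-876 16 and 9. Quantile normalization gave 24 and 6 for TNF alone and 10 and 7 for TNF after BAY-876. With BAY-876 under TNF 36 rose and 1 fell, and 26 and 3 with quantile normalization. Genes of the mitochondrial genome, 13 in number, were higher in OT1 cells in 6 and lower in 0, against 6 and 1 with quantile normalization, beside the same myeloid means. In culture 2 rose and 5 fell with BAY-876 at 32 h and 1 and 6 under TNF, and 2 and 6 and 1 and 7 with quantile normalization. The counts were 1 and 0 with BAY-876 at 36 h, 1 and 3 with TNF alone and 1 and 2 with TNF after BAY-876, and 0 and 1, 1 and 1, and 3 and 2 with quantile normalization. Histone genes had 1 call on day 16 and 0 in culture.

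The erythroid list, which holds hemoglobin genes, varied widely within both cell types. It averaged 36.2, 2.02, 9.46, 180 and 26.6 TPM in tumour libraries 1 to 5 and 228, 13.0, 55.2, 556 and 38.2 in OT1 libraries 1 to 5. Replicate 4 was highest and replicate 2 lowest in both, although the labels do not say that a number marks a mouse.

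Splits of 3 against 3 libraries number 10, too few for a share under 0.05. The real counts were 1868 at 36 h, 4776 for BAY-876 and 5826 for TNF at 32 h, 5644 for TNF after BAY-876 and 4341 for BAY-876 under TNF, and the highest counts of other splits were 3, 1, 1, 2 and 1. On day 16 the real split called 10059 genes and the highest of the other splits, among 100 in all, 2. Every other split mixes both cell types within a group, which widens the spread and keeps its count low. The splits show only that the count follows the sort, and the libraries may be technical replicates.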
